A study of Mus musculus with 3 samples.

How the data were processed

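RNA from mouse cardiomyocyte preparations of 3 ages was hybridised to Illumina expression bead arrays, on which each probe is carried by many beads. Per the labels, the ages were embryonic day 11 to 12, postnatal day 3 to 4, and adult at 10 weeks or older. The strain label names eGFP with α-MHC, the product of Myh6, on the DBA background. The design text states that RNA of several hearts was pooled within a sample and that hearts were dissociated with a Liberase enzyme blend. It speaks of samples for FACS, but the gate used to keep or discard cells is not given in the sources used here. Per the labels' protocols, RNA was extracted with Trizol, treated with DNase I on a Qiagen column and checked on an Agilent Bioanalyser, and biotin-labelled cRNA was made with an Ambion MessageAmp kit. The scanner software and the version of the array are not given in the sources used here.

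The authors deposited a raw table of probe intensity for 46632 probes, per the file headers with the spread between beads, the number of beads and a detection score for each probe. The intensity was on a linear scale with no background subtracted, since no value was at or below 0. The deposited detection score rose with the signal towards its maximum for bright probes, so its complement was used as a detection p. The authors also deposited a matrix of processed intensity, again linear. In its adult column the values were the raw intensity minus a constant near 48.5, and its embryonic and neonatal columns kept the raw order of probes with about the adult distribution. Its medians were 8.74 for the embryonic, 8.75 for the neonatal and 8.74 for the adult array, and 27.9% of its values in the adult column lay below 0. The method by which the authors set the embryonic and neonatal columns to that distribution is unknown. Another deposited table held the authors' comparisons of adult with embryonic and adult with neonatal as a ratio and a natural log, per the file headers. Each of its ratios equalled the quotient of the processed columns within a relative tolerance of 0.001, and the log was missing for 8296 probes in adult over embryonic and 7097 in adult over neonatal, where the ratio was negative. A further 25 probes were in the processed matrix and not in the raw table, and were not used here.

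The raw intensity was the starting point of all main values. The neqc function of limma 3.58.1 in R 4.3.3 estimated each array's background from the detection p, subtracted it with a normal plus exponential model and an offset of 16, quantile normalized the 3 arrays and took log2. Quantile normalization gives every array the same distribution, so a shift common to all genes of a stage cannot be seen. The background estimate was 63.7 for the embryonic, 65.0 for the neonatal and 49.8 for the adult array. The offset draws differences of dim probes towards 0.

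Probes were named through the RefSeq gene table of assembly GRCm38.p6, which served for names and for the chromosome a gene lies on, with no coordinates. An accession matched for 11875 probes and a file symbol or its synonym for 22852, giving 20973 genes. Another 134 probes whose accession and file symbol named different genes were left out, and 11771 probes kept the file's own name and did not enter counts of genes. Of the named genes, 8567 had several probes, and the probe with the highest mean log2 signal over the 3 arrays stood for the gene.

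No test was possible with 1 array of pooled RNA per stage, and no p-value is given across genes. Instead, a gene counted as higher or lower where its log2 values differed by at least 1 (2-fold) and its detection p was under 0.01 in at least 1 array of the pair. Where only 1 array of the pair detected the gene, the dim side was replaced by the higher of its own value and the lowest value among probes detected on that array, and the difference is a bound, written as at least N-fold. That lowest value was 6.27 for the embryonic, 5.93 for the neonatal and 6.26 for the adult array on the log2 scale. The value after ± is the standard error of a difference from the spread between beads. It measures the precision of a single array and leaves out the variation between animals, preparations and hybridisations.

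A gene list was described by the median log2 difference of its measured members, those detected in at least 1 array of the pair. Its place was taken among 10000 random lists of the same size, drawn from measured genes in the same 20 bins of mean log2 signal. A list is said to stand apart where its median lay outside the central 95% of matched lists. That describes these arrays and is no test of the stages. There were 23 functional lists and 17 lists of cell type markers, and a median was given for lists with at least 3 measured members. The lists, the rule of size and the rule for named genes were fixed before the data were examined.

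The genes named are the 6 with the largest increase and the 6 with the largest decrease among those detected in both arrays of a comparison, and the 3 with the largest bound each way among those detected in 1 of them, leaving out RIKEN, LOC, Gm and clone names. Added to these are the members furthest apart in each functional list with the member furthest in the opposite direction, up to 5 measured members of each cell type list or its 3 brightest, and in every array Myh6, Myh7, Tnni1, Tnni3, Myl2, Myl7, Nppa, Mki67, Igf2 and Cpt1b. Other genes are said to have been chosen after their values were seen. A few genes that these rules pick are not reported here.

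The rule of size was tested on simulated data, in which a pair of arrays was drawn from the embryonic array's signals and bead errors and 50 probes each, of middle to high signal, were changed by 1.5-fold, 2-fold, 3-fold or 5-fold. It called 0 probes of the 50 changed by 1.5-fold, 21 of those changed by 2-fold, and 50 of 50 at 3-fold and at 5-fold, and 7 of 14547 unchanged probes. The simulated arrays varied only by bead error and background noise. These counts therefore leave out variation between animals, preparations and hybridisations. Of 100 simulated unchanged lists of 15 genes, 6.0% lay outside the central 95%. The number of arrays limits the precision of every value.

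Alternatives to the main setting were quantile normalization without background correction, centring on the median of detected probes in place of quantile normalization, an offset of 50, the authors' processed values and their deposited comparisons, no detection filter, detection in both arrays, a detection p of 0.05, a threshold of 3-fold and the mean over a gene's probes. Counts over all probes, normalization without the adult array and a requirement on bead error were added after the data were seen. Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.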

Results

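Gene expression was measured in cardiomyocyte preparations from mouse hearts at 3 ages, to compare embryonic, neonatal and adult stages with each other. Each stage was represented by 1 bead array, so no value below has a replicate. The embryonic array detected 14066 probes (30.2%), the neonatal array 15355 (32.9%) and the adult array 14115 (30.3%). Raw probe signals had medians of 72.2, 77.6 and 57.3 in the same order, and a probe was read from a median of 37 beads on each array. Over the 11197 probes detected on all arrays, the log2 signals correlated across probes at 0.90 between neonatal and adult, 0.81 between embryonic and neonatal, and 0.71 between embryonic and adult. Probes are not independent replicates.

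The gene whose promoter is named in the reporter, Myh6 for α-myosin heavy chain, was at log2 11.40 in the embryonic array and 9.68 in the neonatal array. It was not detected in the array labelled adult, where its value was 5.83. Other cardiomyocyte genes were detected there, among them Myl2 for the ventricular regulatory light chain at 10.61 and Tnni3 for cardiac troponin I at 8.62, against 14.99 and 13.62 in the embryonic array. Transcripts of other cell types were bright in the neonatal and adult arrays. Of 15 fibroblast markers on the array, 5 were detected in the embryonic, 14 in the neonatal and 14 in the adult array. Their median rank among detected genes, with undetected markers at the bottom, was 96.7% in the neonatal and 96.9% in the adult array. Of 16 macrophage markers, the embryonic array detected 4, the neonatal 14 and the adult 15. Every difference between stages described here was measured on arrays that differ in these markers too.

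**Figure D1:**
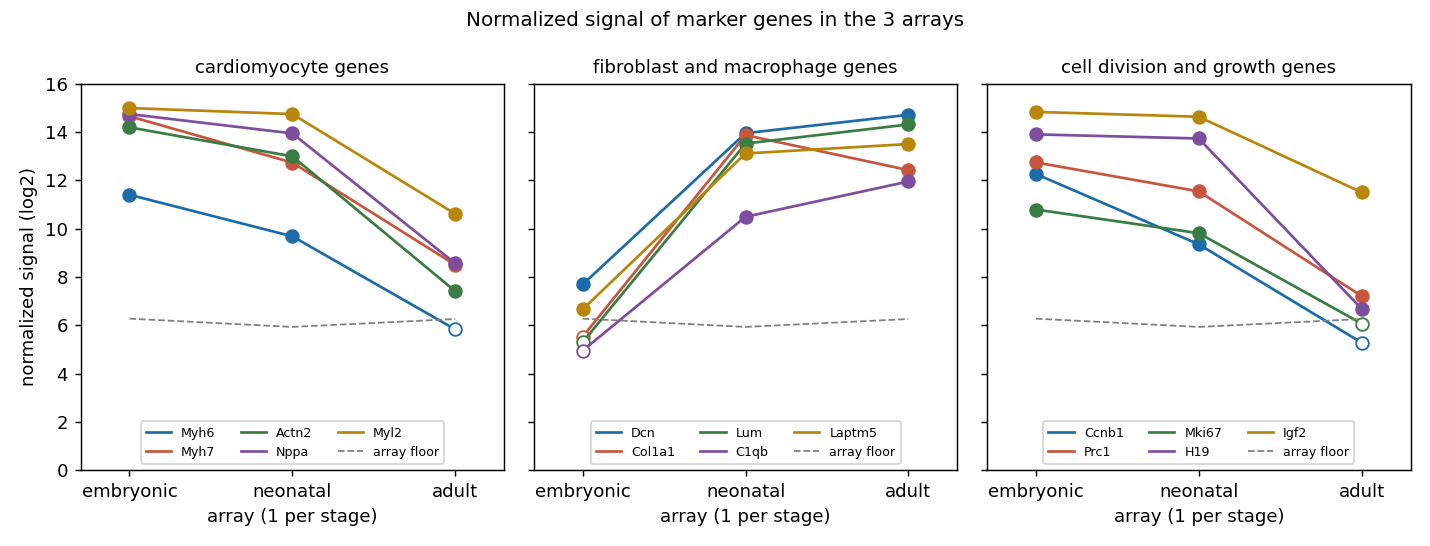
Normalized log2 signal of 15 genes on the y axis in the embryonic, neonatal and adult arrays on the x axis, with 1 array per stage, filled points for detected genes, open points for genes not detected, and a dashed line for the lowest detected signal of each array. Myh6 lies at 11.40, 9.68 and 5.83 across the arrays, and Dcn at 7.69, 13.95 and 14.71.

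Between the embryonic and neonatal arrays, genes of connective tissue were far higher in the neonatal array, and many genes of the contractile apparatus, energy metabolism and cell division were lower. Cxcl1, a chemokine that attracts neutrophils, was 226-fold higher in the neonatal array (log2 difference 7.82 ± 0.17). Mmp2, a gelatinase of the matrix, was higher by 7.55 ± 0.11 and the fibrillar collagen gene Col3a1 by 7.07 ± 0.18. Nppb, encoding brain natriuretic peptide, was 28.1-fold lower (-4.81 ± 0.11). In all, 3678 of 10559 measured genes were at least 2-fold apart, 1863 higher and 1815 lower in the neonatal array, and 516 were over 8-fold apart. The higher genes made up 50.7% of them, but 1180 of the 2683 that were detected in both arrays.

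The extracellular matrix list had 28 of 31 measured members at least 2-fold higher in the neonatal array and 0 lower, with a median difference of 4.11. Col1a1, for type I collagen, was at least 193-fold higher, and Lum, for the keratan sulfate proteoglycan lumican, at least 151-fold. The versican gene Vcan differed by 0.60. Col6a3 and Fbln2, for a type VI collagen chain and fibulin 2, were higher by 7.33 ± 0.13 and 6.99 ± 0.12. Dpt and Mfap5, for the matrix proteins dermatopontin and microfibril-associated protein 5, were at least 226-fold and 190-fold higher. Emp1, for an epithelial membrane protein, was higher by 7.63 ± 0.12. Fibroblast markers, 6 of which are also in the matrix list, had 13 of 14 measured members higher and a median of 6.15. The proteoglycan gene Dcn was 76.8-fold higher and the receptor gene Pdgfra 32.8-fold, and Fbln1 differed by 0.97.

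Markers of immune and vessel cells were higher as well. Macrophage markers had 13 of 15 measured members higher and 1 lower, with a median of 3.38, and Laptm5, of lysosomes in blood cells, was 87.3-fold higher while Lyz2 differed by 0.28. Smooth muscle and pericyte markers were higher in 8 of 12 and lower in 1, with a median of 3.00. Mylk, for myosin light chain kinase, was higher by 4.15 and Acta2 differed by 0.08. The endothelial list was higher in 7 of 12 measured members with a median of 1.59, Esam being 34.9-fold higher and Egfl7 differing by -0.19. Endocardial markers were higher in 4 of 5 with a median of 1.69, of which Edn1, for endothelin 1, was higher by 2.82; with the mean over probes the median was 1.11, among matched lists. Neutrophil markers were higher in 4 of 5 with a median of 1.80, S100a8 and S100a9 being at least 9.93-fold and 10.2-fold higher, and did not stand apart in the authors' processed values. Platelet markers were higher in 2 of 3 with a median of 1.95, Pf4 by 4.08, but the median turned to -0.24 without a detection filter and was 1.04, among matched lists, with the mean over probes. With only genes detected in both arrays, the median was 0.00 for endothelial and 0.56 for smooth muscle markers, and both then lay among matched random lists.

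Some genes of the heart muscle cell were lower in the neonatal array and others stayed under 2-fold. Of 11 measured genes of the fetal cardiac program, 6 were at least 2-fold lower and 1 higher, with a median of -1.92. Acta1, for skeletal α-actin, differed by -3.61, Tnni1, for slow skeletal troponin I, by -3.34 ± 0.08, and the stress-responsive gene Ankrd1 by -3.25. Tagln, of smooth muscle, was 2.05-fold higher. The sarcomere list had 13 of 25 lower and 2 higher, with a median of -1.03. Among its members, Nebl differed by -3.84, Mybpc3, for cardiac myosin-binding protein C, by -3.51 and Myom1 by -3.33, whereas Tpm1, for tropomyosin 1, was 17.1-fold higher. The Tpm1 value rests on 1 probe, with raw signals of 292.0 in the embryonic and 5593.4 in the neonatal array. Which transcripts of the gene that probe reads was not examined. Myh7, for β-myosin heavy chain, differed by -1.92 ± 0.08, Myh6 by -1.73 ± 0.12 and Tnni3 by -1.03 ± 0.04. Myl2, Myl7 and Nppa stayed under 2-fold, at -0.25 ± 0.07, -0.93 ± 0.06 and -0.80 ± 0.05. Their raw embryonic signals of 35253.8, 31107.6 and 29995.7 were near the array's maximum of 39259.2. So close to the top of the scale a larger difference may not be seen, which was not tested.

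Calcium handling genes were lower in 11 of 17 with a median of -1.50, the calsequestrin gene Casq1 at least 19.3-fold and the exchanger gene Slc8a1 at -2.53. Intercalated disc genes were lower in 7 of 13 and higher in 1, with a median of -1.48, or -0.45 and among matched lists without a detection filter. The desmosome genes Pkp2, Dsg2 and Dsp differed by -3.70, -3.49 and -3.35, and Jup by 1.17. Cardiac transcription factors were lower in 13 of 25 and higher in 4, with a median of -1.30; Nkx2-5 was 15.4-fold lower and Hey1 3.26-fold higher. Ion channel genes were lower in 8 of 18 and higher in 5, with the potassium channel gene Kcnj8 at least 9.59-fold higher. Their median of -0.43 lay among matched lists but stood apart at -1.27 with only genes detected in both arrays and at -0.54 without a detection filter. Atrial markers, with 0 of 5 lower and 1 higher, lay among matched lists at -0.80 and stood apart at -0.77 without the filter. Ventricular markers had a median of -1.77, with Hey2 at -2.68.

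Many genes of energy metabolism were lower in the neonatal array. Glycolysis genes were lower in 16 of 18 with a median of -1.69, and Slc2a1, the GLUT1 transporter, was 11.7-fold lower. Fatty acid oxidation genes were lower in 13 of 24 with a median of -1.15, with Acadl at -3.14 and Cpt1b, the muscle carnitine palmitoyltransferase, at -2.56 ± 0.07. Citric acid cycle genes were lower in 11 of 19 and higher in 1 with a median of -1.32, Mdh1 being 7.24-fold lower. Respiratory chain genes were lower in 26 of 47 with a median of -1.06. Among metabolic regulators the nuclear receptor gene Esrrg was at least 25.3-fold lower and the creatine kinase gene Ckm 3.70-fold higher, and the list's median of -0.24 lay among matched lists.

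Many genes of cell division were lower too. DNA replication genes were lower in 18 of 29 with a median of -1.20, Rrm2, for ribonucleotide reductase, being 7.05-fold lower. Mitosis genes were lower in 19 of 28 with a median of -1.32, Ccnb1, for cyclin B1, being 7.49-fold lower and Top2a 5.49-fold, while Mki67 differed by -0.99 ± 0.08 and Ccnd1 by 0.84. Fetal RNA-binding and high-mobility-group genes were lower in 4 of 7 with a median of -1.19, with Igf2bp1 at -3.36, and lay among matched lists at -0.68 with the mean over probes. Erythroid genes were lower in 9 of 13 with a median of -1.87, or -0.97 and among matched lists with only genes detected in both arrays. Embryonic globin genes were seen in the embryonic array alone: Hbb-y was at least 155-fold, Hba-x at least 145-fold and Hbb-bh1 at least 140-fold lower in the neonatal array. The adult globin genes Hba-a1 and Hbb-b1 differed by -0.97 and 0.65. Slc4a1, the band 3 anion exchanger of red cells, differed by -4.34 ± 0.21.

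Immediate early and dissociation stress genes were higher in 15 of 24 and lower in 0, with a median of 1.44; Klf2 was 40.2-fold and Junb 6.83-fold higher. MHC class I and antigen processing genes were higher in 7 of 12 with a median of 2.22, H2-D1 by 3.73. BMP and TGFβ genes were higher in 8 of 17 and lower in 2 with a median of 0.77, Tgfbr2 being 28.7-fold higher and Bmp7 at least 32.7-fold lower, and without a detection filter the median was 0.17, among matched lists. Lists among matched random lists were imprinted growth genes at -0.18, ribosome genes at -0.02, circadian genes at 0.40, cell cycle inhibitors at -0.10 and antioxidant genes at -0.31. Within the imprinted list Dlk1 was higher by 4.32 ± 0.05 and Igf2 differed by -0.20 ± 0.09. Epicardial, Schwann and neuronal, hepatocyte and skeletal muscle markers also lay there, at 0.73, 0.00, -0.37 and -0.58. Skeletal muscle markers stood apart at -3.61 and circadian genes at 0.66 with only genes detected in both arrays, and epicardial markers at 1.03 without a detection filter and at 0.73 with the mean over probes. Lymphocyte and adipocyte markers had 1 measured member each, and lung epithelial markers 0. Outside the lists, the glycogenin gene Gyg, the scaffold gene Homer2, the lysophosphatidic acid receptor gene Lpar3 and Upp1, for uridine phosphorylase, differed by -4.66, -4.63, -4.34 and -4.26.

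Between the neonatal and adult arrays, sarcomere, fetal cardiac and mitosis genes were far lower in the adult array, and genes of antigen presentation, of macrophages and of the immediate early response were higher. H19, an imprinted noncoding RNA, was 132-fold lower (-7.05 ± 0.14), and Dlk1, an imprinted Notch ligand homologue, 56.2-fold (-5.81 ± 0.08). Actn2, for the Z-disc protein α-actinin 2, differed by -5.58 ± 0.14. Gsn, for the actin-severing protein gelsolin, was 76.6-fold higher (6.26 ± 0.10). In all, 2267 of 10403 measured genes were at least 2-fold apart, 1156 higher and 1111 lower in the adult array, and 214 were over 8-fold apart. The higher genes made up 51.0% of them, and 67.5% where arrays were centred on their medians.

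Sarcomere genes were lower in 18 of 24 measured members and higher in 0, with a median of -3.21. The cardiac actin gene Actc1 differed by -5.18 ± 0.08, the titin gene Ttn was at least 24.4-fold lower, and Pdlim5 differed by 0.73. Over the 15 sarcomere genes detected in both arrays the median was -4.13, with quartiles of -4.31 and -2.99. Fetal cardiac genes were lower in 10 of 11, with a median of -3.63. Nppa, for atrial natriuretic peptide, differed by -5.38 ± 0.07, Myh7 by -4.23 ± 0.12 and Myl4 by -4.06, and Acta2 by -0.42. Myh6 was at least 10.7-fold lower and Tnni1 at least 7.22-fold. Myl2, Myl7 and Tnni3 differed by -4.13 ± 0.07, -3.95 ± 0.09 and -3.97 ± 0.06. Atrial markers had a median of -3.95 with 4 of 5 lower, and ventricular markers -2.84 with 3 of 4 lower. The skeletal muscle list, which holds Acta1 at -4.17, had a median of -1.18 that turned to 0.02 without a detection filter.

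Calcium handling genes were lower in 7 of 16 with a median of -0.83, with the ryanodine receptor gene Ryr2 at -4.38 and the phospholamban gene Pln at -3.03. Ion channel genes were lower in 8 of 16 and higher in 2 with a median of -0.90, Kcne1 at least 6.71-fold lower and Fxyd1 2.90-fold higher, and with only genes detected in both arrays their median was -0.08. Intercalated disc genes were lower in 7 of 13 with a median of -1.40, Gja5, for connexin 40, at least 9.22-fold. Cardiac transcription factors were lower in 9 of 21 with a median of -0.81, with the cofactor gene Myocd at -3.13. Macrophage markers were higher over the same pair of arrays.

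Respiratory chain genes were lower in 13 of 46 with a median of -0.79, with the muscle isoforms Cox6a2 and Cox8b at -3.64 and -3.09. Glycolysis genes were lower in 3 of 16 and higher in 2 with a median of -0.46, the muscle isoforms Pgam2 and Eno3 differing by -4.92 and -3.91 and the platelet-type phosphofructokinase gene Pfkp by 1.70. Fatty acid oxidation genes were lower in 2 of 23, these being the heart fatty acid-binding protein gene Fabp3 at -4.16 and Cpt1b, at least 12.2-fold lower. The list's median was -0.10. Citric acid cycle genes were lower in 6 of 18 with a median of -0.44, with Idh2 at -2.01, and metabolic regulators in 4 of 15 with a median of -0.23, with Mb, for myoglobin, at -2.70. The medians of glycolysis, fatty acid oxidation, citric acid cycle and regulator genes lay among matched lists, but that of citric acid cycle genes stood apart at -0.40 with median centring and at -0.44 without background correction, with an offset of 50 and in the authors' processed values.

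Mitosis genes were lower in 21 of 24 with a median of -3.07, with Prc1 at -4.34 and Kif23 at -3.94, both of the central spindle, and Mki67, the Ki-67 proliferation antigen, was at least 11.7-fold lower. DNA replication genes were lower in 20 of 27 with a median of -1.52, with Uhrf1 at -4.28. Cell cycle inhibitor genes had a median of 0.72 with 4 of 13 higher and 1 lower, Gadd45a being 4.78-fold and Cdkn1a, for p21, 3.21-fold higher. Imprinted growth genes were lower in 8 of 14 and higher in 2 with a median of -1.42. Mest differed by -5.04, Igf2 by -3.12 ± 0.11 and Gnas by 1.18. Fetal RNA-binding genes were lower in 3 of 4 with a median of -2.83, Igf2bp3 being at least 20.3-fold lower, and lay among matched lists at -0.15 without a detection filter.

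MHC class I and antigen processing genes were higher in 14 of 15 with a median of 1.98, H2-T23 by 4.48 and B2m, for β2-microglobulin, by 0.81. H2-Ea, of MHC class II, was higher by 6.20 ± 0.09. Macrophage markers were higher in 9 of 15 with a median of 1.34, Lyz2, for lysozyme, by 4.23. Immediate early genes were higher in 13 of 25 and lower in 1 with a median of 1.05, Fosb being 11.3-fold and Egr2 7.82-fold higher. Circadian genes were higher in 8 of 14 and lower in 1 with a median of 1.20. Npas2 and Arntl, of the activating limb of the clock, were 4.23-fold and 3.22-fold higher, and Dbp, an output gene, 3.07-fold lower. Antioxidant genes were higher in 7 of 17 with a median of 0.38 and BMP and TGFβ genes in 4 of 15 with a median of 0.38. The glutathione transferase gene Mgst1 was 14.3-fold and the latency protein gene Ltbp1 3.16-fold higher. With arrays centred on their medians these lists lay just among matched lists, and without a detection filter the BMP and TGFβ median was 0.01.

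Fibroblast markers had a median of 0.39 with 3 of 14 higher and 3 lower, or 0.21 and among matched lists without a detection filter, the bright Dcn, Dpt and Lum differing by 0.75, 0.21 and 0.79. Matrix genes were lower in 10 of 31 and higher in 4 with a median of -0.41, or -0.04 with arrays centred on their medians and -0.19 with the mean over probes, both among matched lists. Eln, for elastin, was 8.27-fold and the tenascin gene Tnc 6.75-fold lower, and Timp1, for a metalloproteinase inhibitor, 3.92-fold higher. Neutrophil markers were lower in 4 of 6 with a median of -1.41. Hepatocyte markers were higher in 3 of 4 with a median of 2.66, Trf, for transferrin, by 3.07, but without a detection filter the median was 0.04, among matched lists. Endocardial, smooth muscle, epicardial, and Schwann and neuronal markers lay among matched lists at -0.18, -0.22, 0.03 and 0.45, as did ribosome genes at -0.22, though Schwann and neuronal markers stood apart at 1.27 with only genes detected in both arrays and at 0.72 with the mean over probes. Endothelial markers were there too with 1 of 13 higher and 3 lower, and erythroid genes with 2 of 7 lower. Lymphocyte and platelet markers had 2 measured members each, and adipocyte markers 1. Outside the lists, the largest bounds were for Inmt, an indolethylamine methyltransferase, and the chemokines Cxcl14 and Ccl11, at least 230-fold, 115-fold and 111-fold higher. Hsd11b1, which regenerates active glucocorticoid, the interferon-inducible Ifi207, the surface antigen gene Ly6a and the glutathione transferase gene Gsta3 were higher by 6.25, 6.06, 5.93 and 5.91. The kinase gene Nrk was at least 53.2-fold, the amino acid transporter gene Slc38a4 at least 22.0-fold and the collagen gene Col26a1 42.3-fold lower.

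Between the embryonic and adult arrays, muscle, cell division and metabolic genes were lower in the adult array, and genes of fibroblasts, matrix and macrophages were higher. Acta1 was 221-fold lower (-7.79 ± 0.21), and Smyd1, for a muscle histone methyltransferase, 136-fold (-7.09 ± 0.14). Cxcl1 was 347-fold higher (8.44 ± 0.17), and C3, the central complement component, at least 364-fold. In all, 4668 of 10541 measured genes were at least 2-fold apart, 2255 higher and 2413 lower, and 1035 were over 8-fold apart. Higher genes made up 48.3% of them, 43.6% (1362 genes) with only genes detected in both arrays, and 58.7% where arrays were centred on their medians, which moved the median of all genes from -0.14 to 0.02.

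Fetal cardiac genes had 9 of 11 members lower and a median of -6.15, sarcomere genes 20 of 25 lower and 1 higher with a median of -4.38, and calcium handling genes 13 of 17 lower and 2 higher with a median of -3.00. Nppb was at least 142-fold lower, Myh7 71.1-fold and Nppa 72.4-fold. Actn2 differed by -6.78 ± 0.14, Synpo2l, of the Z-disc, by -6.59 and Ryr2 by -6.38, while Tpm1, read from the same probe as above, was 8.67-fold higher. Myh6 was at least 35.4-fold and Tnni1 at least 73.4-fold lower, and Tnni3, Myl2 and Myl7 were 32.1-fold, 20.8-fold and 29.5-fold lower. Atrial, ventricular and skeletal muscle markers had medians of -4.33, -4.24 and -2.56. Intercalated disc genes were lower in 8 of 13 and higher in 1 with a median of -1.85, Gja5 at least 51.0-fold lower, but with only genes detected in both arrays the median was -0.96, among matched lists. Cardiac transcription factors were lower in 16 of 25 with a median of -1.45, with Hopx at -4.84. Ion channel genes were lower in 7 of 16 and higher in 3 with a median of -0.55, among matched lists, Kcne1 being at least 33.6-fold lower and Kcnj8 at least 9.05-fold higher, and stood apart at -0.52 without a detection filter.

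Respiratory chain genes were lower in 41 of 47, citric acid cycle genes in 15 of 19, glycolysis genes in 17 of 18 and fatty acid oxidation genes in 15 of 23, with 2 higher, with medians of -1.84, -2.00, -1.85 and -1.66. Pgam2 differed by -6.59 ± 0.12, Cox6a2 by -4.96, and Cpt1b was at least 72.3-fold lower, while Lpl, for lipoprotein lipase, was 2.71-fold higher. Metabolic regulators were lower in 9 of 15 and higher in 4 with a median of -1.61, the coactivator gene Ppargc1a being at least 16.9-fold lower and the nuclear receptor gene Ppard 3.53-fold higher. Their median lay among matched lists at -0.49 without a detection filter and at -0.55 with only genes detected in both arrays. Mitosis genes were lower in 24 of 28 and DNA replication genes in 28 of 29, with medians of -4.30 and -2.74. Ccnb1 was at least 64.0-fold, Rrm2 at least 38.1-fold and Mki67 at least 23.2-fold lower. Imprinted growth genes were lower in 9 of 14 and higher in 2 with a median of -2.09, H19 differing by -7.22 ± 0.13, Igf2 by -3.32 ± 0.10 and Dcn, also a fibroblast marker, by 7.01. Fetal RNA-binding genes were lower in 4 of 7 with a median of -2.88, Igf2bp3 being at least 59.7-fold lower. Erythroid genes had a median of -1.54, with Hbb-y at least 123-fold lower, but lay among matched lists at -0.76 with only genes detected in both arrays. Ppp1r1a, for a protein phosphatase inhibitor, was at least 123-fold lower.

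Higher in the adult than in the embryonic array were 14 of 14 measured fibroblast markers with a median of 6.22, 29 of 31 matrix genes with a median of 3.25, and 15 of 15 macrophage markers with a median of 5.04. The fibroblast and matrix counts partly repeat the same genes, since the lists share 6 members. Prelp, of the matrix, and Serping1, an inhibitor of complement, were at least 357-fold and 291-fold higher. Mgp, Serpinf1 and Rarres2, for matrix Gla protein, pigment epithelium-derived factor and the chemoattractant chemerin, were higher by 7.46, 7.46 and 7.34, and Emp1 and Mmp2 by 7.57 and 7.36. MHC class I genes were higher in 13 of 15 with a median of 3.66, immediate early genes in 19 of 25 with a median of 2.30, circadian genes in 9 of 15, with 1 lower, with a median of 1.09 and BMP and TGFβ genes in 8 of 17, with 2 lower, with a median of 0.71. Ifitm3 was at least 243-fold, Klf2 147-fold, Rora 10.1-fold and Tgfbr2 61.0-fold higher, while Dbp was 2.09-fold and Bmp7 at least 26.1-fold lower. Endothelial markers were higher in 7 of 12 and lower in 2, smooth muscle markers higher in 7 of 12 and lower in 1, and epicardial markers higher in 5 of 9 and lower in 3, and these lists stood above matched lists. With only genes detected in both arrays their medians were 0.55, -0.24 and -0.98, among matched lists, and without a detection filter the epicardial median of 0.26 lay there too. Cell cycle inhibitor, antioxidant and ribosome genes lay among matched lists at 0.40, 0.01 and -0.25, with Cdkn1a 7.54-fold higher and Cdkn1c 4.60-fold lower, and the inhibitors stood apart at 0.83 with median centring. Endocardial, neutrophil, platelet, Schwann and neuronal, and hepatocyte markers also lay there, at 1.09, 0.58, 1.77, 0.72 and 1.12, with 2 lymphocyte markers and 1 adipocyte marker measured. Of these, endocardial markers stood apart at 1.92 with only genes detected in both arrays, neutrophil markers at 0.85 and Schwann and neuronal markers at 0.26 without a detection filter, platelet markers at 1.42 with an offset of 50, and hepatocyte markers at 0.94 without background correction and at 1.12 with the mean over probes.

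**Figure D2:**
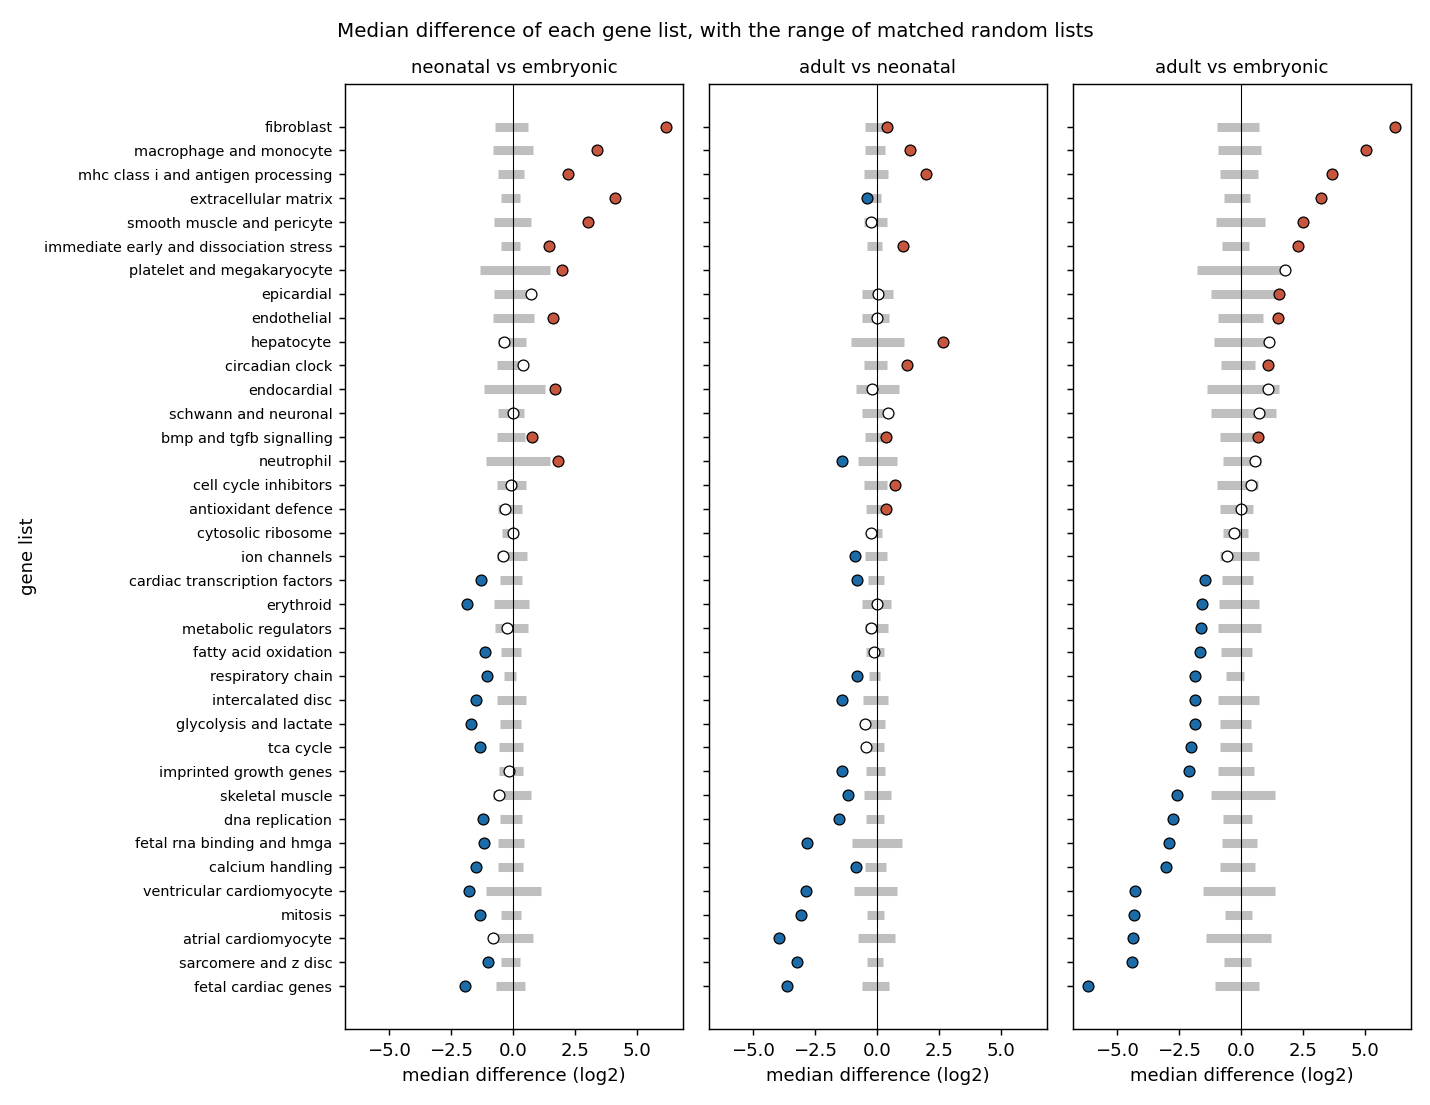
Median log2 difference of each gene list on the x axis for each pair of arrays, with grey bars for the central 95% of 10000 matched random lists and points coloured where the median lay above (red) or below (blue) them. Fibroblast markers lie at 6.15 in neonatal against embryonic and at 0.39 in adult against neonatal, and sarcomere genes at -1.03 and -3.21.

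Across both steps, 10041 genes could be followed. Of these, 390 were at least 2-fold higher at each step, 326 lower at each step, 278 highest in the neonatal array, 143 lowest there, 2276 apart at the first step alone, 962 at the second alone and 5666 at neither. With only genes detected in both arrays of a step, 170 were higher and 188 lower at each step and 151 highest in the neonatal array, and genes lowest there numbered 90 with an offset of 50 and 81 without background correction. Both steps share the neonatal array, so its chance errors push genes towards a peak or a trough. Genes lower at each step included 15 of 24 mitosis genes, such as Ccnb1, Cdk1, Plk1 and Aurkb, 12 of 27 replication genes, such as Mcm2, Mcm5 and Rrm2, and 9 of 24 sarcomere genes, such as Myh6, Ttn and Mybpc3. Genes higher at each step included 7 of 15 macrophage markers, such as Csf1r and C1qa, 9 of 24 immediate early genes, such as Fosb and Klf2, and 6 of 12 MHC class I genes, such as H2-D1 and Psmb8. A neonatal peak was seen for 10 of 31 matrix genes, such as Col1a1, Postn, Eln and Lox, and for 4 of 5 neutrophil markers.

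The authors' deposited table gave the same direction as the values here for 2244 of 2244 genes called between adult and neonatal and for 4407 of 4407 between adult and embryonic that it held. That table was computed from processed columns that kept the raw order of probes on the same arrays. Because both sides rest on the same signals, agreement in direction was largely fixed beforehand and is no independent check. The authors' deposited values put 2813 and 5086 genes at least 2-fold apart. These counts used the deposited ratios, with no dim side replaced by a bound, unlike the calls made here. Differences in the authors' deposited table, converted from natural logs to log2, were -7.07 for H19 and -5.45 for Actc1 between adult and neonatal. Where a called gene had further detected probes, these went the same way in 84.7% of cases for neonatal against embryonic, 82.9% for adult against neonatal and 91.2% for adult against embryonic. Fewer of them reached 2-fold the same way, at 421 of 711, 220 of 432 and 540 of 828 probes in that order. At least 2-fold the opposite way were 26, 5 and 18 probes.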

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

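Counts over all probes, normalization without the adult array and the bead error requirement were tests chosen after the results were seen. Each stage had a single array, so signal over background limits the dim genes and no alternative can show the variation between hearts. No paired analysis was possible because each stage had 1 sample and the labels give no replicate numbers. The cause was not tested for any value below, except where a stricter or wider selection of genes changes a count by its construction. Neonatal against embryonic, 3-fold gave 1978 genes, 1125 higher and 853 lower. Genes detected in both arrays gave 1180 higher, the same with the bead error requirement, and all probes gave 5913 with 3218 lower. Adult against neonatal, 3-fold gave 984 genes, 535 higher and 449 lower, and all probes 3572 with 1958 higher. Adult against embryonic, 3-fold gave 2851 with 1341 lower, genes detected in both arrays or with the bead error requirement 1362 higher, and all probes 3677 lower. The remaining 91 of 108 counts stayed within 1.5 times the main count. For stage patterns, genes detected in both arrays gave 170 higher and 188 lower at each step and 151 neonatal peaks, and troughs numbered 90 with an offset of 50 and 81 without background correction.

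Of 762 list medians under alternatives, 712 kept their side of the matched range. Without a detection filter, neonatal against embryonic, the platelet list turned to -0.24, disc genes were at -0.45, BMP and TGFβ genes at 0.17 and no longer apart, and ion channels at -0.54, epicardial markers at 1.03 and atrial markers at -0.77 stood apart. Adult against neonatal without the filter, skeletal muscle markers turned to 0.02, and fetal RNA-binding genes at -0.15, BMP and TGFβ genes at 0.01, fibroblast markers at 0.21 and hepatocyte markers at 0.04 no longer stood apart. Adult against embryonic without the filter, regulators at -0.49 and epicardial markers at 0.26 no longer did, and ion channels at -0.52, neutrophil markers at 0.85 and Schwann and neuronal markers at 0.26 did.

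With detection in both arrays, neonatal against embryonic, endothelial markers at 0.00, smooth muscle markers at 0.56 and erythroid genes at -0.97 no longer stood apart, and ion channels at -1.27, circadian genes at 0.66 and skeletal muscle markers at -3.61 did. Adult against neonatal, ion channels at -0.08 no longer did, and Schwann and neuronal markers at 1.27 did. Adult against embryonic, smooth muscle markers turned to -0.24 and epicardial markers to -0.98, disc genes at -0.96, regulators at -0.55, endothelial markers at 0.55 and erythroid genes at -0.76 no longer stood apart, and endocardial markers at 1.92 did.

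With the mean over a gene's probes, neonatal against embryonic, fetal RNA-binding genes at -0.68, endocardial markers at 1.11 and platelet markers at 1.04 no longer stood apart and epicardial markers at 0.73 did. Adult against neonatal, matrix genes at -0.19 and BMP and TGFβ genes at 0.38 no longer did, Schwann and neuronal markers at 0.72 did, and the heat shock gene Hspa1a turned from -1.20 to 0.24. Adult against embryonic, hepatocyte markers stood apart at 1.12. With median centring, adult against neonatal, matrix genes at -0.04, BMP and TGFβ genes at 0.41 and antioxidant genes at 0.49 no longer stood apart, and adult against embryonic cell cycle inhibitors did at 0.83. Citric acid cycle genes, adult against neonatal, stood apart at -0.40 with median centring and at -0.44 without background correction, with an offset of 50 and with the authors' processed values. Hepatocyte markers without background correction (0.94) and platelet markers with an offset of 50 (1.42) stood apart for adult against embryonic, and neutrophil markers with the processed values (1.85) did not for neonatal against embryonic. Of 3550 values of named genes, 2987 moved by less than their bead error, or by under 1 for a bound; 562 moved further, with an offset of 50 or without background correction always to a smaller size (85 and 123) and with the processed values always to a larger one (58).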

Other observations

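The genes and sets in the next paragraph and all tests in this part were chosen after the results were seen. MHC class II and complement genes made up sets that no list above covers as a whole, although Cd74 and the C1q genes are also macrophage markers. All 8 class II genes measured were at least 2-fold higher in the adult than in the neonatal array, with a median difference of 5.28. Cd74, the invariant chain, was at log2 8.08 in the neonatal and 13.97 in the adult array, and H2-Ab1 and H2-Eb1 were detected in the adult array alone, at 12.30 and 12.48. The 12 complement genes measured were also all at least 2-fold higher in the adult array, with a median of 2.76. C3 was at 11.67 in the neonatal and 14.78 in the adult array, C4a at 7.52 and 13.01, and Serping1 at 12.07 and 14.46. In the embryonic array C3, C4a, Serping1 and Cd74 were not detected.

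Cardiomyocyte genes were lower and fibroblast genes higher in the adult than in the embryonic array, although all preparations are labelled cardiomyocytes. Array brightness or normalization argues poorly for this, since the sarcomere median of -4.38 lies far below the -0.67 that bounds matched lists, and the median stayed outside under each normalization tried. RNA of cells other than cardiomyocytes in the adult library may contribute. The parts of the pattern came mostly at different steps. Fibroblast markers had a median of 6.15 for neonatal against embryonic and of 0.39 for adult against neonatal. The sarcomere medians were -1.03 and -3.21 in the same order. Other cells in the adult library alone would thus leave the neonatal rise in fibroblast markers unexplained. Macrophage markers, which are in no other list, were detected in the adult array in 15 of 16 cases with a median rank of 84.7%, Laptm5 being at 13.50. A sort that kept only reporter cells would remove cells of other types, but whether the cells on these arrays were so sorted is not stated. Myh6, the gene named in the reporter, was itself not detected in the adult array, at 5.83. The macrophage markers were also higher than in the embryonic array in 15 of 15 measured cases, with a median of 5.04. They moved with the fibroblast genes and were seen beforehand, so they are no independent check. A smaller cardiomyocyte share with the other cells unchanged was taken to raise all their markers alike. Over the few genes detected in both arrays, 5 fibroblast and 4 endothelial, the medians lay 5.75 apart on the log2 scale. The 95% bootstrap interval of 1.56 to 8.06 is over genes of 1 pair of arrays, not over hearts. Within the endothelial list alone, Egfl7 differed by -1.77 and Esam by 4.34. Markers of 1 cell type thus did not move alike, and this comparison cannot decide. A change in fibroblasts with age, and a change of cardiomyocytes themselves, stay open and untested.

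Imprinted growth genes were lower in the adult than in the neonatal array. Setting these falls beside those of sarcomere genes bears on a smaller cardiomyocyte share only if cardiomyocytes supply the imprinted transcripts, which was not measured. In the imprinted list, 2 members, H19 and Dlk1, lay below Actn2 at -5.58, the lowest of the sarcomere genes detected in both arrays. The other 6 of the 8 lower members did not. Dlk1 at -5.81 ± 0.08 is not clearly apart from Actn2 (± 0.14), so by bead error only H19 at -7.05 clearly lay below. Between the embryonic and neonatal arrays, 3 of 15 measured imprinted genes were higher and 4 lower in the neonatal array. Dlk1 and Meg3 were higher there by 4.32 and 2.30, while the sarcomere median was -1.03. The comparison with sarcomere genes therefore cannot decide. For the list as a whole the share and a loss with age stay open.

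Y-linked genes were not detected in the adult array, although Ddx3y was not detected in the embryonic array either. Eif2s3y, a translation factor gene of the Y chromosome, was at log2 10.22 in the embryonic and 10.34 in the neonatal array and at least 17.0-fold lower in the adult than in the neonatal array, while the X-inactivation transcript Xist was at 9.12, 10.70 and 11.24. Lower sensitivity of the adult array argues poorly for Eif2s3y, since only 1.0% of 1497 genes as bright in the neonatal array went undetected in the adult array, but for the dimmer Kdm5d it stays open, at 27.7% of 1503 genes, and for Ddx3y it was not tested. Only female hearts in the adult pool is a candidate explanation that rests on Eif2s3y. Xist was higher by 0.53 ± 0.07 in the adult than in the neonatal array, and by 0.50 to 0.54 under the normalizations tried. That is under 2-fold. Xist also went from 9.12 in the embryonic to 10.70 in the neonatal array, while Eif2s3y was at 10.22 and 10.34. The Xist difference therefore cannot decide. If the adult pool was female only, sex would differ with stage in every comparison that uses the adult array.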
